A study of Homo sapiens with 12 samples.

How the data were processed

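Total RNA of BEAS-2B cells was labelled with biotin by the Affymetrix whole-transcript kits, per the labels' protocols, and measured on 12 arrays. The deposited table holds linear intensities for 28869 probesets per array, and how the authors summarised, background-corrected or scaled them is not given in the sources used here. The quantiles of the 12 columns are nearly equal, so the arrays had been put on one scale before deposit. No further normalization was applied, and log2 was taken (values under 1 would have been set to 1; none was that low). Arrays have no read depth, and their number limits the precision: the median SE of a log2 change was 0.071 for 2 arrays against 2 and 0.043 for all PM arrays against the untreated ones.

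Groups came from the labels: untreated, normal PM and storm PM on day 1 and day 4, with 2 arrays each. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between arrays of a group and nothing wider. All 12 arrays entered a single limma fit with 1 mean per group (R 4.3.3, limma 3.58.1), which left 6 residual and 3.73 prior degrees of freedom. There were 11 comparisons: normal PM and storm PM against untreated cells on each day, storm against normal PM on each day and over both days, any PM against untreated cells over both days, untreated day 4 against day 1, and the change of each PM response between the days as an interaction. Adjusted p are Benjamini-Hochberg values over all probesets, with a call at an adjusted p under 0.05. Simulated data with 200 changed probesets in each of 5 runs of 28869 gave back, for normal PM on day 1, 85.6% of 1.5-fold and 98% of 2-fold changes, with 6% of calls false. For storm against normal PM on day 1 the shares were 84.8% and 97.2%, for the normal PM interaction 56.8% and 88.4%, and for any PM 97.6% and 100%. The simulated noise was independent between probesets and arrays. The share of false calls therefore does not cover array differences that many probesets have in common, as the real arrays do.

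The annotation lists 21062 of the probesets, 19310 with 1 gene symbol and 1752 with several, and 7807 are not listed. Only probesets with 1 symbol are named, which covers 18377 genes. No coordinates are given, since the table used names no genome build.

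Before the data were examined, 31 gene lists, the comparisons, the rule for naming genes and most alternative settings were fixed. The lists came from general knowledge of particles, metals, hydrocarbons, oxidative stress and epithelial cells. They include markers of leukocytes, endothelial cells and fibroblasts, and small nucleolar RNAs as a sign of RNA quality. Several genes are in more than 1 list, for example HMOX1, NQO1, SLC7A11, SQSTM1 and COL1A1. Of the lists 30 were tested with camera from limma at a preset correlation of 0.01, on the brightest probeset of each gene, with Benjamini-Hochberg adjustment over the lists of a comparison. None of the mitochondrially encoded mRNAs was measured under its symbol, so 0 members of that list could be tested. In simulated data camera called 25 of 25 lists shifted by 0.2 on the log2 scale and 0 of 100 unshifted ones. The simulated noise was independent between probesets, so the 0 of 100 does not test for false calls from correlated genes. Counts adjusted over the list alone use the members' own p-values, and camera was repeated with a correlation estimated from the residuals. Of 135 list calls, 12 held with the estimated correlation.

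Genes were named by rule: the 10 largest rises and 10 largest falls called with no overlap between the groups' arrays, up to 4 members of each called list, 7 genes kept in the tables of every comparison (CYP1A1, CYP1B1, HMOX1, NQO1, MT2A, IL6 and CXCL8), and the 10 with the largest mean change among those called alike in most PM comparisons. The text gives a part of the genes so named. Where no probeset passed, the 5 highest and 5 lowest changes at an unadjusted p under 0.001 are given as values only.

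The alternatives were other normalizations (median centring, quantile normalization), an offset of 16, leaving out dim probesets, only probesets with 1 symbol, a fold threshold, an intensity trend with a robust prior, array weights, the compared groups alone, the replicate number as a block, fry in place of camera, the mean of a gene's probesets, and leaving out each array. Added after the data had been seen were the array median as a covariate, leaving out the pair of untreated arrays with the highest medians, the other pairs of 1 untreated array per day, and a crossed replicate block.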

Results

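Gene expression was measured with whole-transcript Affymetrix arrays in BEAS-2B cells, a line of human bronchial epithelial cells. The cells were left untreated or were given airborne particulate matter (PM) from Saudi Arabia at 50 µg per cm3, the unit the labels give. The particles had been collected either in normal weather or in storm weather, and the cells were sampled on day 1 or day 4. The 12 arrays form 6 groups of 2: untreated, normal PM and storm PM on each day. Each array gave an intensity for 28869 probesets, and the small number of arrays limits the precision of every value. Differences are given as log2 fold changes with their standard error (SE) from limma, and a change was called at an adjusted p under 0.05.

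Arrays of the same group were close, with Pearson correlations of log2 intensity of 0.9972 to 0.9987 across probesets, which are not independent replicates. The standard deviation of the log2 difference between the arrays of a group ran from 0.106 with normal PM on day 4 to 0.157 in untreated cells on day 1. Median intensity was 190 on untreated day 1 array 1 and on untreated day 4 array 2, and 179.4 to 185.9 on the other arrays. The same pair of untreated arrays lay farthest out on the second principal component, which held 28.5% of the variance, at 19.68 and 20.27. The other untreated arrays were at 6.88 and 10.62 there, and the 8 PM arrays were between -11.83 and -0.66. The first component held 31.2% of the variance and separated day 1 from day 4.

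The first question was which genes differed with particles of either kind, averaged over both days. IL24 (probeset 7909271), a cytokine of the interleukin-10 family, rose most, 5.83-fold (log2 2.54, SE 0.05, 8 PM arrays against 4 untreated). MMP1 (7951271), a collagenase, rose 3.67-fold (log2 1.87, SE 0.05), and GPNMB (8131844), a glycoprotein of lysosomes and melanosomes, rose 3.45-fold (log2 1.79, SE 0.04). RRAGD (8128123), a GTPase of nutrient sensing at the lysosome, rose 2.91-fold (log2 1.54, SE 0.06), and CYP1B1 (8051583), a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 2.26-fold (log2 1.18, SE 0.04). TNFRSF11B (8152512), which encodes osteoprotegerin, was 3.21-fold lower (log2 -1.68, SE 0.06). DIO2 (7980485), an iodothyronine deiodinase, was 3.17-fold lower (log2 -1.66, SE 0.04). SULF1 (8146863), a heparan sulfate sulfatase, fell by 1.59 (SE 0.04), NPPB (7912520), a natriuretic peptide, fell by 1.26 (SE 0.04) and IGFBP3 (8139488), which binds insulin-like growth factors, fell by 1.21 (SE 0.04) on the log2 scale. These 10 genes were called in the same direction in all 4 comparisons of a PM group with its untreated group. In limma 2144 probesets rose and 1677 fell, which name 1846 and 1352 genes, and 135 of the 3821 changed by over 1.5-fold. The count was 2338 without untreated day 1 array 1, 2157 without untreated day 4 array 2 and 1557 without both, and it was 2095 with the array median as a covariate.

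**Figure D1:**
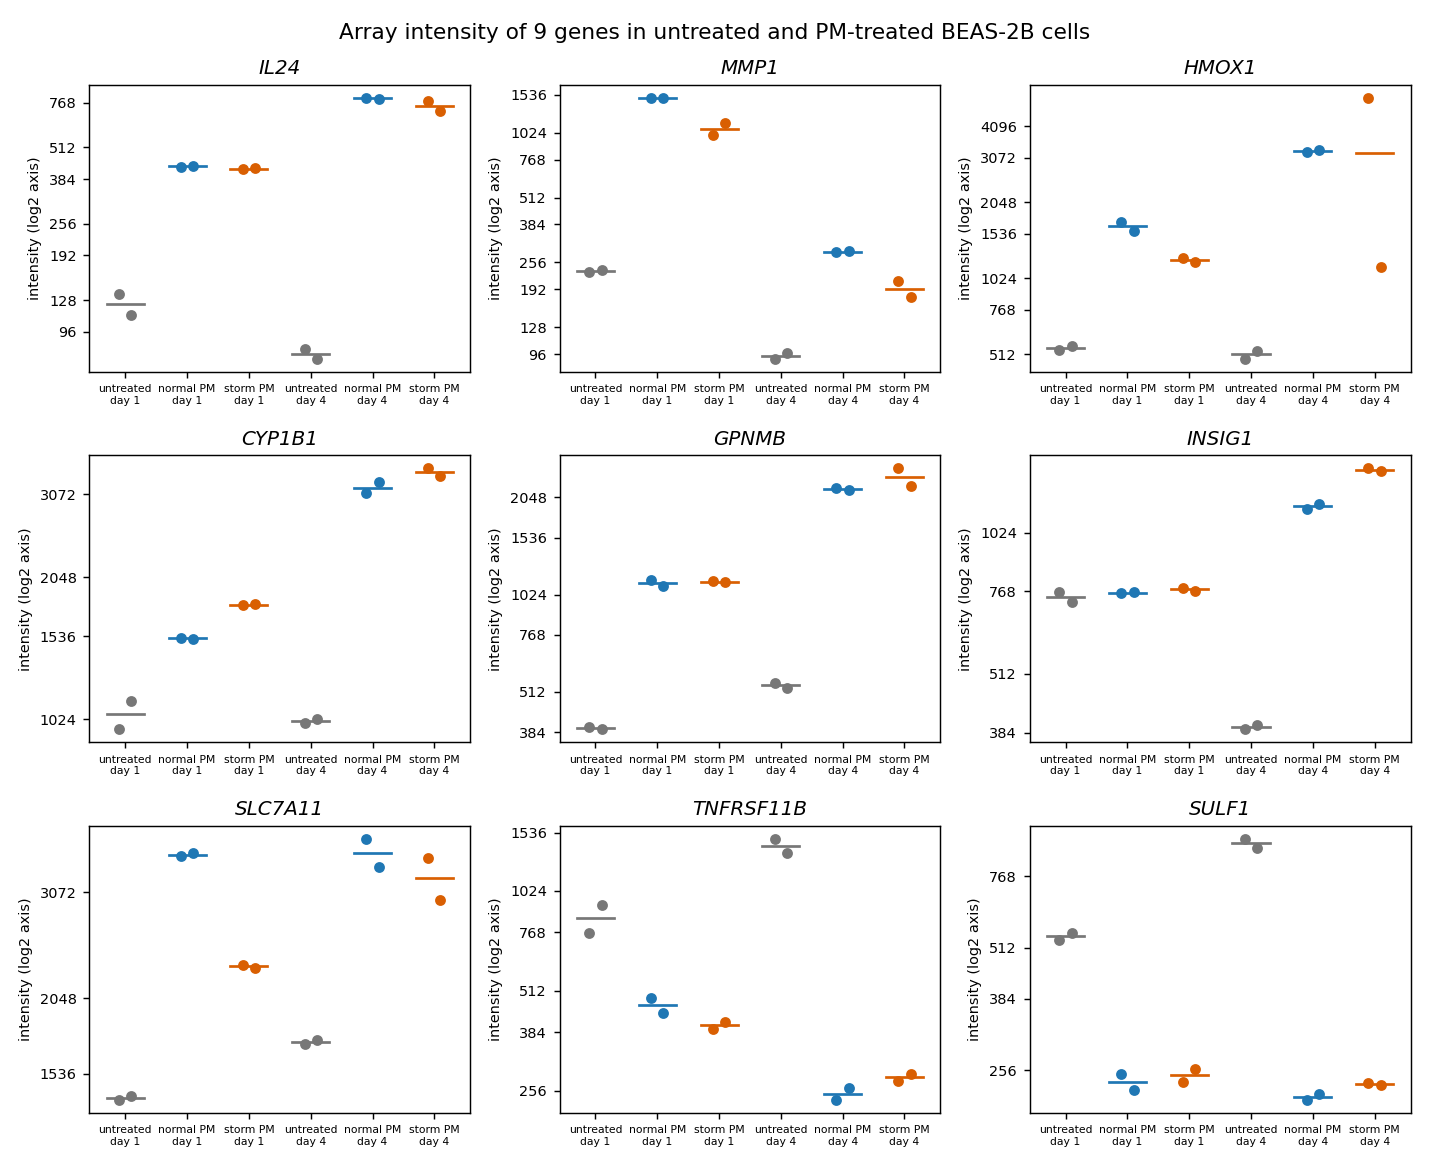
Intensity of 9 genes on a log2 axis, with 1 point per array and a line at the mean of 2 arrays, for untreated cells, normal PM and storm PM on day 1 and day 4. IL24 rises from a mean of 78.84 in untreated cells to 799.2 with normal PM on day 4, and HMOX1 spreads from 1135 to 5302 between the storm PM arrays of day 4.

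Genes of oxidative stress, metals and foreign compounds were higher with PM. Of 23 measured targets of NRF2, the main regulator of antioxidant enzymes, 17 rose and none fell for PM on both days (19 rose when adjusted over the list alone; camera adjusted p = 2.61e-15, and adjusted p = 0.0889 with an estimated correlation). SLC7A11 (8102800), the cystine transporter, rose by 1.00 (SE 0.05), AKR1C3, an aldo-keto reductase, by 0.93 (SE 0.09), and NQO1, a quinone reductase, by 0.91 (SE 0.04) on the log2 scale. HMOX1 (8072678), heme oxygenase, rose 3.8-fold (log2 1.92, SE 0.31, adjusted p = 0.00313), and its call was lost without untreated day 1 array 1 and day 4 array 2 together (adjusted p = 0.053). All 9 measured metallothionein and zinc export genes rose, also adjusted over the list alone (median log2 0.29; camera adjusted p = 4.55e-08, and adjusted p = 0.0889 with an estimated correlation), with MT1X at 0.76 and MT1F at 0.54. Of 11 measured aryl hydrocarbon receptor targets, 5 rose and none fell (6 rose adjusted over the list alone; camera adjusted p = 0.000555, and adjusted p = 0.0889 with an estimated correlation). CYP1A1, the receptor's classic target, rose by 0.30 (SE 0.07, adjusted p = 0.016), but its adjusted p was 0.0743 without untreated day 1 array 1, 0.055 without untreated day 4 array 1, 0.102 without the untreated arrays of highest median and 0.067 with the array median as a covariate. Among 10 iron-handling genes 4 rose, likewise adjusted over the list alone (camera adjusted p = 0.00298, and adjusted p = 0.121 with an estimated correlation), led by HMOX1 and by FTL, the ferritin light chain, at 0.68.

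Genes of amino acid stress and of lysosomes were higher as well. Of 25 measured genes of the ATF4 response to amino acid shortage, 16 rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 4.53e-10, and adjusted p = 0.0931 with an estimated correlation). DDIT3, the stress transcription factor CHOP, rose by 0.98 (SE 0.16), and STC2, a secreted stanniocalcin, rose by 0.75 (SE 0.04). Of 21 genes of lysosomes and particle uptake, 11 rose and none fell (13 adjusted over the list alone; camera adjusted p = 3.61e-08, and adjusted p = 0.0834 with an estimated correlation), among them SQSTM1, an autophagy receptor, at 0.70, and the protease CTSL at 0.62. Of 14 heat shock genes 7 rose and none fell (8 adjusted over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.257 with an estimated correlation). CHORDC1 rose by 0.32 and HSPH1 by 0.32, but their adjusted p were 0.0564 and 0.14 with the array median as a covariate and 0.122 and 0.183 without the untreated arrays of highest median. That of HSPH1 was 0.0799 without untreated day 1 array 1 and 0.071 without untreated day 4 array 2. Of 19 immediate early genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000555, and adjusted p = 0.403 with an estimated correlation), with PHLDA1 at 0.53 and FOSL1 at 0.46. Small nucleolar RNAs, followed as a sign of RNA quality, moved with these groups: 23 of 176 rose, also adjusted over the list alone (median log2 0.04; camera adjusted p = 0.000274, adjusted p = 0.403 with an estimated correlation and 0.497 with the array median as a covariate).

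Genes of lipid synthesis rose while genes of the extracellular matrix fell. Of 18 measured cholesterol synthesis genes 15 rose and none fell (16 adjusted over the list alone; median log2 0.31; camera adjusted p = 2.69e-14), a call that held with an estimated correlation (adjusted p = 0.0255). INSIG1, which holds back sterol synthesis and is itself induced with it, rose by 0.87 (SE 0.03), and HMGCS1, an enzyme of the mevalonate pathway, rose by 0.72 (SE 0.04). For both genes this average joined unlike days. On day 4 INSIG1 was at 1.56 with normal PM and 1.82 with storm PM, and HMGCS1 at 1.29 and 1.37. Those responses exceeded the ones of day 1 by 1.53 and 1.77 for INSIG1, and by 1.18 and 1.25 for HMGCS1. Of 14 genes of fatty acid synthesis and lipid storage 8 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 9.4e-05, and adjusted p = 0.216 with an estimated correlation), with the desaturase SCD (7929816) at 1.08 and the elongase ELOVL6 at 0.68. Of 23 extracellular matrix and TGF-beta target genes none rose and 15 fell (20 adjusted over the list alone; median log2 -0.31; camera adjusted p = 9.36e-14), which also held with an estimated correlation (adjusted p = 0.0414). FN1, fibronectin, was at -0.76 (SE 0.03), THBS1, thrombospondin, at -0.52 (SE 0.04) and the actin-binding TAGLN at -0.49 (SE 0.03). Markers of fibroblasts, a cell type not named in the labels, were lower beside them: 3 of 10 fell (5 adjusted over the list alone; median log2 -0.09; camera adjusted p = 0.0269, and adjusted p = 0.216 with an estimated correlation), with PDGFRB at -0.66. COL1A1, which is in both lists, was at -0.41. That fibroblast call was lost without untreated day 1 array 2 (adjusted p = 0.0568) and without normal PM day 4 array 2 (adjusted p = 0.0522).

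Complement, epithelial and replication genes were lower with PM, and cytokine genes went both ways. Of 14 complement and acute phase genes none rose and 7 fell (2 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.00869, and adjusted p = 0.0889 with an estimated correlation), with CFB, complement factor B, at -0.53 and C3 at -0.38. Of 16 genes of epithelial junctions and keratins 2 rose and 6 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.00556, and adjusted p = 0.0949 with an estimated correlation), with KRT7 at -0.80 and the transcription factor ELF3 at -0.49. Of 25 DNA replication genes none rose and 10 fell (13 adjusted over the list alone; median log2 -0.10; camera adjusted p = 3.68e-05, and adjusted p = 0.0889 with an estimated correlation), with UHRF1 at -0.30 and the helicase subunit MCM5 at -0.29. Of 19 replication-dependent histone genes 9 fell and none rose (12 adjusted over the list alone; median log2 -0.12; camera adjusted p = 2.5e-05, and adjusted p = 0.249 with an estimated correlation). Among 26 inflammatory cytokines and NF-kB targets 5 rose, IL24 among them, and 6 fell (7 and 7 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.409). CXCL8, the neutrophil chemokine interleukin-8, rose by 0.23 (SE 0.03), and IL6 was at 0.00 (95% interval -0.08 to 0.09, adjusted p = 0.967). Matrix proteases were not called as a list (4 of 14 rose and 2 fell, likewise adjusted over the list alone; camera adjusted p = 0.0826), with a median of -0.01, a mean of 0.18 and a test directed upward. On day 1 alone that list was called upward with normal and with storm PM, neither with an estimated correlation. MMP1 was at 2.67 and 2.19 there, and MMP3 at 0.82 and 0.55.

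Some of these averages joined unlike values on single days or for single kinds of PM. CYP1A1 was called on day 4, at 0.49 with normal PM (adjusted p = 0.0307) and 0.53 with storm PM (adjusted p = 0.0225), calls lost without any 1 of 5 and of 4 arrays (adjusted p up to 0.211 and 0.145), without the untreated arrays of highest median (0.0592 and 0.0546) and with the array median as a covariate (0.0552 and 0.061). With normal PM it was lost with the compared groups fitted alone too (0.0673). On day 1 CYP1A1 was not called, at 0.02 (95% interval -0.22 to 0.27) and 0.17 (-0.08 to 0.42), and neither was its difference between the days (0.47 and 0.36; adjusted p = 0.366 and 0.566). CXCL8 rose with normal PM, by 0.25 on day 1 (adjusted p = 0.035) and 0.39 on day 4 (adjusted p = 0.00305), the first call being lost without any 1 of 9 arrays (adjusted p up to 0.184) and in 5 other settings (up to 0.227). With storm PM CXCL8 was not called, at 0.16 (adjusted p = 0.202) and 0.10 (adjusted p = 0.311), and storm against normal PM over both days was at -0.19, not called either (adjusted p = 0.788). MT2A, a metallothionein, was called for any PM at 0.20 (SE 0.03). It was called on day 1, at 0.24 with normal PM (adjusted p = 0.0478) and 0.26 with storm PM (adjusted p = 0.0448), but not without any 1 of 10 arrays (adjusted p up to 0.247 and 0.263) or in 7 other settings (up to 0.21 and 0.272). After quantile normalization MT2A was at 0.17 with storm PM (adjusted p = 0.0993). On day 4 it was not called, at 0.19 and 0.11. IL6 was not called in any of the 4 comparisons, with values from -0.06 to 0.14.

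The next comparison set normal PM against untreated cells on day 1. MMP1 rose 6.36-fold (log2 2.67, SE 0.08, n = 2 per group), from a mean intensity of 233.5 ± 4.26 (SD) to 1485 ± 1.74. IL24 rose 3.5-fold (log2 1.81, SE 0.09), GPNMB 2.81-fold (SE 0.06) and SLC7A11 2.53-fold (SE 0.08). The cell cycle gene CCND1 rose by 1.08, STC2 by 1.03 and the ETS factor ETV5 by 1.02 on the log2 scale. DIO2 was 4.19-fold lower (log2 -2.07, SE 0.07), SULF1 2.28-fold and IGFBP3 2.27-fold lower. The bradykinin receptor BDKRB1 was at -1.12, the growth factor BMP4 at -1.04, the signalling inhibitor SMAD6 at -0.99 and the transcription regulator ID2 at -0.92. NRF2 targets were the most clearly shifted list, with 10 of 23 up and none down (14 adjusted over the list alone; median log2 0.37; camera adjusted p = 2.26e-17, and adjusted p = 0.0981 with an estimated correlation). Extracellular matrix genes were the most clearly lowered, with 1 up and 11 down of 23 (1 and 16 adjusted over the list alone; median log2 -0.24; camera adjusted p = 6.77e-11, and adjusted p = 0.0981 with an estimated correlation), FBN1, fibrillin, being at -0.62.

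Beside the matrix genes, fibroblast markers were lower with normal PM on day 1. Of 10 none rose and 2 fell (3 adjusted over the list alone; median log2 -0.09; camera adjusted p = 0.0224, and adjusted p = 0.234 with an estimated correlation), with PDGFRB at -0.91 and COL1A1, a member of both lists, at -0.56. That call was lost without untreated day 1 array 2 (adjusted p = 0.0566) and without normal PM day 1 array 2 (0.0511), and that of COL1A1 with the compared groups fitted alone (0.0502). Small nucleolar RNAs, the sign of RNA quality, were higher beside both shifted lists, with 3 of 176 called and none adjusted over the list alone (median log2 0.07; camera adjusted p = 1.3e-05, and adjusted p = 0.349 with an estimated correlation). Their call was lost without untreated day 1 array 1 (adjusted p = 0.148) and with fry (0.218). Cholesterol synthesis genes were not called with normal PM on day 1, with a median of 0.04 (camera adjusted p = 0.0657).

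On day 1, 460 probesets were higher and 570 lower with normal PM, of which 59 and 70 changed by over 1.5-fold. In all, 15 of 30 lists were called, and none with an estimated correlation. The count of 1030 fell to 462 without untreated day 1 array 1, 352 without normal PM day 1 array 1 and 316 without normal PM day 1 array 2. It was 160 with the compared groups fitted alone, 670 after median centring and 385 without the untreated arrays of highest median.

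Many of the same leading genes differed with storm PM on day 1. MMP1 rose 4.56-fold (log2 2.19, SE 0.08, n = 2 per group), IL24 3.43-fold (log2 1.78, SE 0.09) and GPNMB 2.83-fold (SE 0.06 on the log2 scale), while STC2 was up by 0.90, CCND1 by 0.87 and CDCP1, a surface receptor, by 0.81. DIO2 was 3.61-fold lower (log2 -1.85), IGFBP3 2.36-fold and SULF1 2.19-fold lower, and BDKRB1 was at -1.12, PLAC8 at -0.98 and KRT7 at -0.86. CYP1B1 rose by 0.78 (adjusted p = 0.000376), a call lost with the compared groups fitted alone (adjusted p = 0.078). Of 23 NRF2 targets 9 rose and none fell (11 adjusted over the list alone; median log2 0.20; camera adjusted p = 5.45e-10, and adjusted p = 0.186 with an estimated correlation). Of 9 metallothionein genes 5 rose (8 adjusted over the list alone; median log2 0.30; camera adjusted p = 5.45e-10, and adjusted p = 0.103 with an estimated correlation). Of 23 extracellular matrix genes none rose and 9 fell (1 and 18 adjusted over the list alone; median log2 -0.25; camera adjusted p = 3.34e-13, and adjusted p = 0.0841 with an estimated correlation). Small nucleolar RNAs were higher beside these, with 132 of 176 above 0 and 1 called (median log2 0.08; camera adjusted p = 3.69e-07, adjusted p = 0.296 with an estimated correlation and 0.14 with fry). HMOX1 was not called on day 1, at 1.16 with storm PM (adjusted p = 0.322) and 1.60 with normal PM (adjusted p = 0.138). Its SE of 0.51 in both came from the fit of all groups, which includes the wide spread between the storm PM arrays of day 4. Those arrays are in neither comparison, so the missing calls do not show that HMOX1 was unchanged on day 1.

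Fibroblast markers were lower beside the matrix genes with storm PM on day 1 too. Of 10 none rose and 2 fell, also adjusted over the list alone (median log2 -0.12; camera adjusted p = 0.0213, and adjusted p = 0.186 with an estimated correlation), with PDGFRB at -0.78 and COL1A1 at -0.50. The list call was lost without untreated day 1 array 2 (adjusted p = 0.0716). With the compared groups fitted alone PDGFRB and COL1A1 were not called (0.0672 and 0.155), nor was COL1A1 without storm PM day 1 array 2 (0.0543). Cholesterol synthesis genes were called upward as a list, with none of 18 called alone or adjusted over the list alone (median log2 0.09; camera adjusted p = 0.0104, and adjusted p = 0.186 with an estimated correlation). CYP51A1 was at 0.25 and LSS at 0.18, and the list call was lost without untreated day 1 array 1 (adjusted p = 0.083), after quantile normalization (0.0517) and with the array median as a covariate (0.054). Interferon-stimulated genes were called upward as well, with 1 of 28 up, likewise adjusted over the list alone (median log2 0.10; camera adjusted p = 0.00917, and adjusted p = 0.186 with an estimated correlation). The called member was HERC5, a ligase of the interferon response, at 0.47, and IFIT2 was at 0.28 (adjusted p = 0.105). HERC5 was not called without any 1 of 11 arrays (adjusted p up to 0.258) or in 5 other settings (up to 0.313), and it was at 0.31 without untreated day 1 array 1 (0.173) and without the untreated arrays of highest median (0.181). The list call was lost without untreated day 1 array 1 (adjusted p = 0.083) and without dim probesets (0.102).

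With storm PM on day 1, 314 probesets rose and 327 fell, with 42 and 45 over 1.5-fold, and 19 of 30 lists were called, none with an estimated correlation. The count of 641 was 221 without untreated day 1 array 1, 1179 without untreated day 1 array 2, 200 and 136 without storm PM day 1 array 1 and array 2, and 404 without either normal PM array of day 4. It was 25 with the compared groups fitted alone, 176 without the untreated arrays of highest median, 379 with array weights, 410 after median centring and 970 with an intensity trend and a robust prior.

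With normal PM on day 4, IL24 was 10.1-fold higher than in untreated cells (log2 3.34, SE 0.09, n = 2 per group), at 799.2 ± 3.21 against 78.84 ± 5.04 (SD). GPNMB rose 4.05-fold, AKR1C3 3.62-fold (log2 1.86, SE 0.15), SCD 3.2-fold, CYP1B1 3.12-fold (log2 1.64, SE 0.07), MMP1 3.04-fold and INSIG1 2.95-fold (log2 1.56, SE 0.05). TNFRSF11B was 5.59-fold lower (log2 -2.48, SE 0.10), SULF1 4.19-fold, NPPB 2.91-fold and FN1 2.15-fold lower, and DHRS3, a retinal reductase, was at -1.39. Of 18 cholesterol synthesis genes 16 rose and none fell (17 adjusted over the list alone; median log2 0.44; camera adjusted p = 3.4e-21, and adjusted p = 0.00827 with an estimated correlation), with HMGCS1 at 1.29, MSMO1 at 0.80 and SQLE at 0.73. Of 23 extracellular matrix genes none rose and 12 fell, also adjusted over the list alone (median log2 -0.32; camera adjusted p = 4.87e-14, and adjusted p = 0.0393 with an estimated correlation). Of 23 NRF2 targets 17 rose and none fell, also adjusted over the list alone (median log2 0.49; camera adjusted p = 2.93e-17, and adjusted p = 0.0859 with an estimated correlation), and NQO1 was at 1.23. Fatty acid genes rose in 8 cases and fell in 2 of 14 (9 and 3 adjusted over the list alone; camera adjusted p = 5.3e-05, and adjusted p = 0.179 with an estimated correlation), with ELOVL6 at 0.86 and FASN at 0.66. Replication-dependent histones fell in 5 of 19 cases (11 adjusted over the list alone; median log2 -0.19; camera adjusted p = 3.97e-08, and adjusted p = 0.156 with an estimated correlation). HMOX1 rose 6.39-fold (log2 2.68, SE 0.51, adjusted p = 0.0146), a call lost without untreated day 4 array 1 (adjusted p = 0.0681) or array 2 (0.078), without normal PM day 4 array 1 (0.0922) or array 2 (0.0983), without the untreated arrays of highest median (0.0998) and with an intensity trend and a robust prior (0.0606).

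Beside the matrix genes, fibroblast markers were also lower with normal PM on day 4, with none of 10 up and 2 down, also adjusted over the list alone (median log2 -0.09; camera adjusted p = 0.0311, and adjusted p = 0.191 with an estimated correlation). PDGFRB was at -0.50 and COL1A1 at -0.32, the latter not called without any 1 of 3 arrays (adjusted p up to 0.141), without the untreated arrays of highest median (0.0848) or with the compared groups fitted alone (0.0725). The list call was lost without untreated day 4 array 2 (adjusted p = 0.062), without normal PM day 4 array 2 (0.12) and after quantile normalization (0.07). Interferon-stimulated genes were called downward with normal PM on day 4, with none of 28 up and 2 down (3 adjusted over the list alone; median log2 -0.10; camera adjusted p = 0.0125, and adjusted p = 0.156 with an estimated correlation). XAF1 was at -0.48 and MX2 at -0.42, MX2 not being called without any 1 of 3 arrays (adjusted p up to 0.12) or without the untreated arrays of highest median (0.0664). The list call was lost without untreated day 4 array 1 (adjusted p = 0.158).

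With normal PM on day 4, 999 probesets were higher and 589 lower, with 134 and 83 over 1.5-fold. Of 30 lists 18 were called, 2 of them with an estimated correlation. The count of 1588 was 1007 and 667 without untreated day 4 array 1 and array 2, 577 and 555 without normal PM day 4 array 1 and array 2, 766 with the compared groups fitted alone and 767 without the untreated arrays of highest median.

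With storm PM on day 4, IL24 rose 9.48-fold (log2 3.24, SE 0.09, n = 2 per group), GPNMB 4.4-fold, SCD 3.71-fold, INSIG1 3.54-fold and CYP1B1 3.37-fold (log2 1.75, SE 0.07). RAB27B, a GTPase of vesicle secretion, rose by 1.52 and ENPP2, which makes lysophosphatidic acid, by 1.39. TNFRSF11B was 4.99-fold lower (log2 -2.32, SE 0.10), SULF1 3.89-fold and NPPB 3.54-fold lower, and FN1 was at -1.13. Of 18 cholesterol synthesis genes 16 rose and none fell, also adjusted over the list alone (median log2 0.53; camera adjusted p = 7.85e-21, and adjusted p = 0.00867 with an estimated correlation), with HMGCS1 at 1.37 and STARD4, a sterol carrier, at 0.96. Of 23 NRF2 targets 15 rose and 1 fell (16 and 1 adjusted over the list alone; median log2 0.44; camera adjusted p = 1.53e-13, and adjusted p = 0.125 with an estimated correlation). Of 23 extracellular matrix genes none rose and 11 fell (14 adjusted over the list alone; median log2 -0.29; camera adjusted p = 1.01e-12, and adjusted p = 0.0506 with an estimated correlation). Fibroblast markers were not called as a list beside them, with a median of -0.14 (camera adjusted p = 0.0717), but 2 of 10 fell (1 rose and 3 fell adjusted over the list alone). Of 21 lysosome and particle uptake genes 9 rose and none fell (12 adjusted over the list alone; median log2 0.19; camera adjusted p = 4.98e-08, and adjusted p = 0.085 with an estimated correlation), CTSL being at 0.70. HMOX1 rose 4.8-fold (log2 2.26, SE 0.51, adjusted p = 0.0311), but its storm PM arrays were at 5302 and 1135 on array 1 and array 2. Its log2 change was 1.15 without array 1 and 3.38 without array 2. With 1 array left in the group their disagreement no longer enters the SE, so these fits do not test the call.

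That HMOX1 call was lost without untreated day 4 array 1 (adjusted p = 0.0944) or array 2 (0.145), without either normal PM array of day 1 (0.0512) or of day 4 (0.0539). It was lost as well with the compared groups fitted alone (0.162), with an intensity trend and a robust prior (0.0935), with the array median as a covariate (0.111) and without the untreated arrays of highest median (0.162). With storm PM on day 4, 988 probesets were higher and 674 lower, with 131 and 69 over 1.5-fold. Of 30 lists 14 were called, 1 of them with an estimated correlation. The count of 1662 was 590 without untreated day 4 array 2, and 552 and 852 without storm PM day 4 array 1 and array 2. It was 465 with the compared groups fitted alone, 644 without the untreated arrays of highest median and 1016 with the array median as a covariate.

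**Figure D2:**
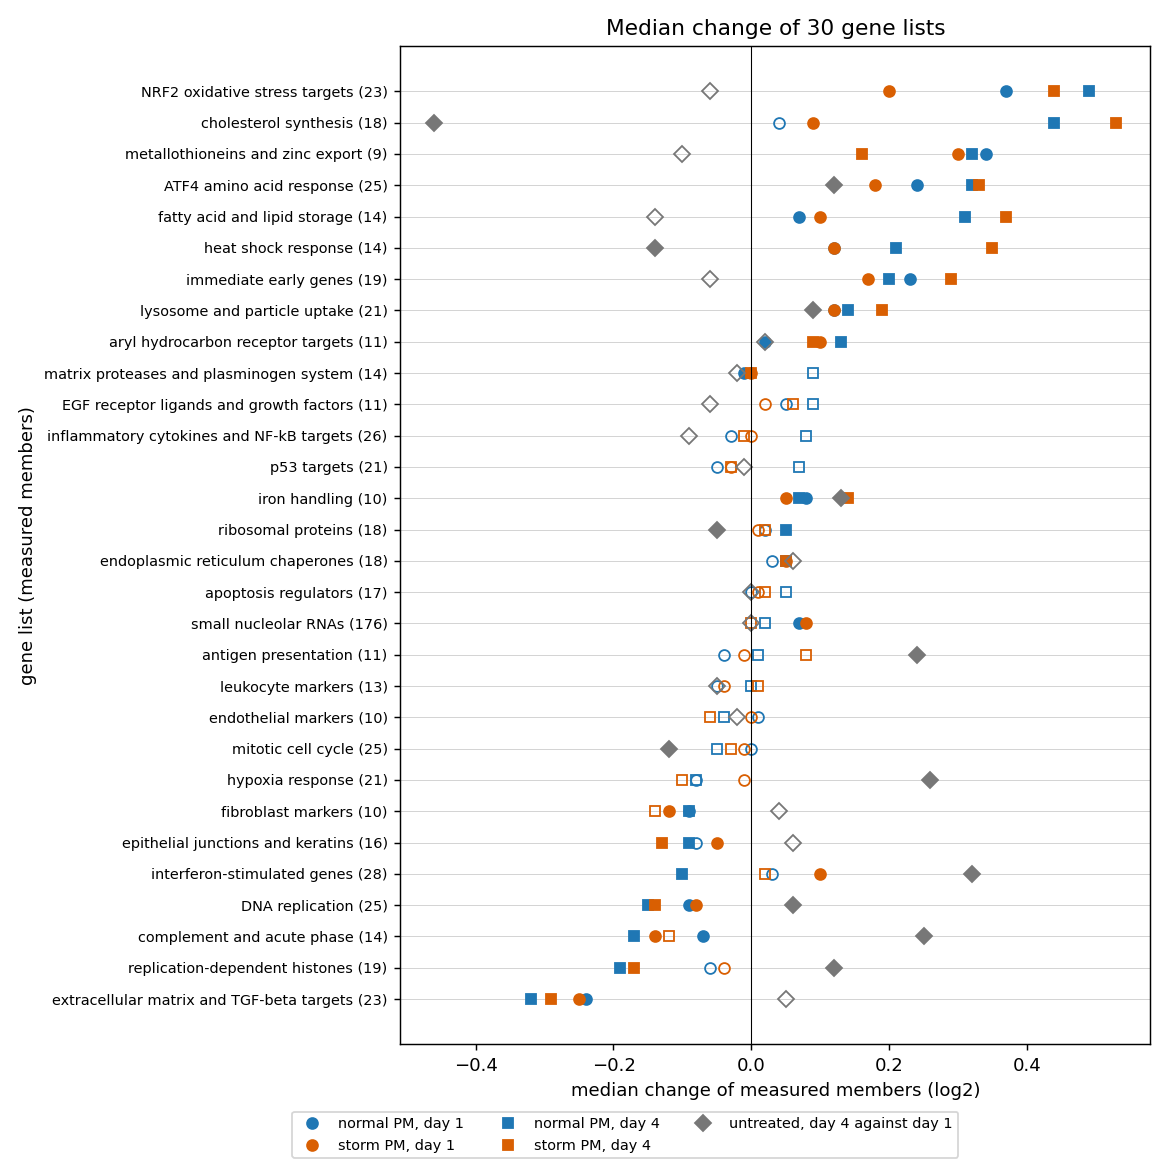
Median log2 fold change of the measured members of 30 gene lists, for 4 comparisons of PM with untreated cells and for untreated cells on day 4 against day 1. Filled points were called by camera with its preset correlation and hollow points were not; the cholesterol synthesis list stands at 0.44 and 0.53 with normal and storm PM on day 4, and at -0.46 in untreated cells over time.

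Normal and storm PM were next compared through their shared changes. On day 1, 272 probesets rose and 295 fell with both kinds of particles, against 5 and 6.5 for independent lists, and none went opposite ways. On day 4 the numbers were 708 and 410, against 34.2 and 13.8, again with none opposite. Across probesets the log2 changes of the 2 kinds of PM had a Pearson correlation of 0.841 on day 1 and 0.854 on day 4. Both kinds share the same untreated arrays, and simulated unchanged groups set against shared controls gave 0.501 and 0.499, so part of the shared calls and of the correlation comes with the shared controls. Day 1 and day 4 share no arrays, and there the correlation was 0.5 for normal PM and 0.529 for storm PM, across probesets that are not independent replicates. Part of it depended on the untreated arrays of highest median. It was 0.384 for normal PM without untreated day 4 array 2, and 0.382 for storm PM without untreated day 1 array 1. Of 2607 probesets called in at least 1 of the 4 comparisons, 174 rose in all 4 and 171 fell in all 4, while 14 went opposite ways in different comparisons.

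**Figure D3:**
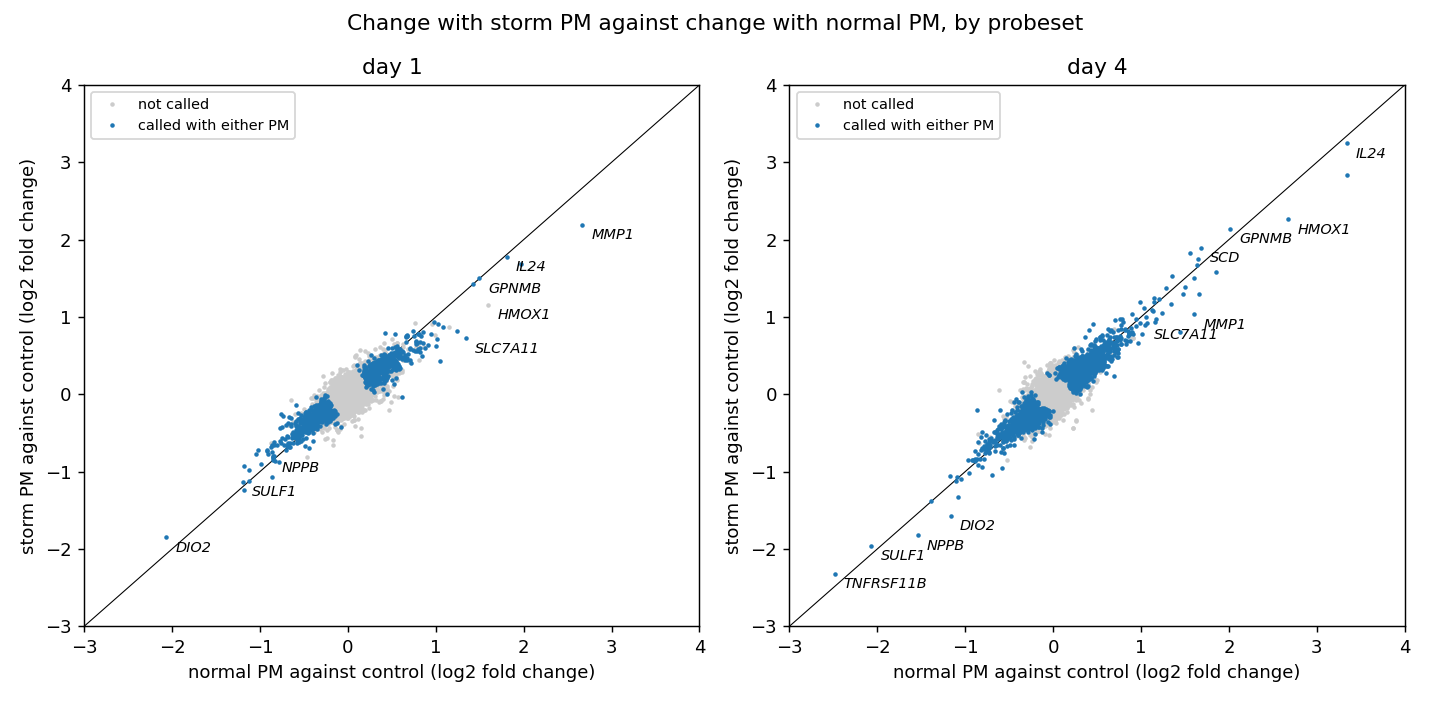
Log2 fold change of each probeset with storm PM against its change with normal PM, both relative to untreated cells, on day 1 and on day 4. Blue probesets were called with either kind of PM, grey ones with neither, and the line marks equal change; the correlation across probesets is 0.841 on day 1 and 0.854 on day 4, of which the shared untreated arrays account for part.

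Set directly against each other, storm and normal PM differed in no single gene by the test used. SLC7A11 showed the widest gap on day 1 among genes named by rule, at -0.62 (95% interval -0.79 to -0.45, n = 2 per group), and MMP1 was at -0.48. On day 4 MMP1 was at -0.57, DIO2 at -0.41 and PLPPR4, a neuronal membrane protein, at 0.46. Averaged over both days, with 4 arrays against 4, MMP1 was at -0.53 (95% interval -0.66 to -0.40, adjusted p = 0.156), SLC7A11 at -0.38 (-0.50 to -0.26), CYP1B1 at 0.17 (0.07 to 0.28), NQO1 at -0.21 (-0.31 to -0.11) and HMOX1 at -0.43 (-1.23 to 0.38), none of them called. In limma no probeset passed on day 1, on day 4 or over both days, while 965, 1513 and 1239 had an unadjusted p under 0.05 where chance gives 1443. With an intensity trend and a robust prior the counts were 1, 0 and 2, and with probesets of 1 gene symbol alone the count over both days was 1. Without storm PM day 4 array 1 they were 14 on day 4 and 17 over both days. The 95% interval lay within 1.5-fold for 98.9% of probesets on day 1, 98.8% on day 4 and 99.8% over both days.

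Small shifts of whole gene lists were seen between the 2 kinds of PM. Interferon-stimulated genes were slightly higher with storm PM over both days, with 27 of 28 members above 0 and none called alone (5 rose adjusted over the list alone; median log2 0.08; camera adjusted p = 1.55e-09), which held with an estimated correlation (adjusted p = 0.0499). NRF2 targets were lower with storm PM, with 20 of 23 members below 0, none called alone and 8 adjusted over the list alone (median log2 -0.10; camera adjusted p = 4.68e-13, and adjusted p = 0.216 with an estimated correlation). On day 1, 2 of 23 NRF2 targets were above 0 (median log2 -0.15; camera adjusted p = 1.37e-15, and adjusted p = 0.204 with an estimated correlation). On day 4 the NRF2 median was -0.08 (camera adjusted p = 0.00196, and adjusted p = 0.779 with an estimated correlation), and without storm PM day 4 array 2 the test turned upward (adjusted p = 0.615). In all 4, 7 and 10 of 30 lists were called on day 1, on day 4 and over both days, and 0, 0 and 1 with an estimated correlation. The other list medians called over both days lay between -0.05 and 0.06.

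Untreated cells changed between day 1 and day 4. SAA1, an acute phase protein, rose 2.99-fold (log2 1.58, SE 0.11, n = 2 per group), the complement proteases C1S and C1R rose 2.74-fold and 2.51-fold, and CFB rose 2.6-fold. BDKRB1 was 3.36-fold lower, DIO2 3.25-fold, IGFBP3 2.77-fold and MMP1 2.48-fold lower. Of 14 complement and acute phase genes 6 rose and none fell (8 and 1 adjusted over the list alone; camera adjusted p = 1.62e-07, and adjusted p = 0.0104 with an estimated correlation). Of 28 interferon-stimulated genes 12 rose and none fell (20 adjusted over the list alone; median log2 0.32; camera adjusted p = 2.08e-16, and adjusted p = 0.00572 with an estimated correlation), with MX2 at 0.91 and MX1 at 0.80. Of 11 antigen presentation genes 5 rose (7 adjusted over the list alone; camera adjusted p = 1.22e-07, and adjusted p = 0.0353 with an estimated correlation), HLA-DMA being at 0.85. Of 21 hypoxia response genes 11 rose and none fell (18 and 1 adjusted over the list alone; median log2 0.26; camera adjusted p = 2.14e-13, and adjusted p = 0.102 with an estimated correlation), with the metastasis suppressor NDRG1 at 1.22 and the lipase inhibitor ANGPTL4 at 1.12. Of 18 cholesterol synthesis genes none rose and 13 fell (15 adjusted over the list alone; median log2 -0.46; camera adjusted p = 6.83e-19, and adjusted p = 0.00572 with an estimated correlation), with HMGCS1 at -1.06 and INSIG1 at -0.92. IL6 rose by 0.61 (adjusted p = 0.000753). Fibroblast markers had a median of 0.04 and were not called (camera adjusted p = 0.373), and neither were small nucleolar RNAs (median log2 0.00, camera adjusted p = 0.946).

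In untreated cells 828 probesets rose and 665 fell over time. The count of 1493 was 961 without day 1 array 1, 727 and 712 without day 4 array 1 and array 2, 178 with the compared groups fitted alone, 343 without the arrays of highest median, 829 with array weights and 2320 with the array median as a covariate. Averaged over both kinds of PM and both days, interferon-stimulated and antigen presentation genes were not called against untreated cells (camera adjusted p = 0.794 and 0.612), nor were hypoxia genes (camera adjusted p = 0.32). For the interferon-stimulated genes that average joins opposite calls, upward with storm PM on day 1 and downward with normal PM on day 4 (medians of 0.10 and -0.10). Neither held with an estimated correlation (adjusted p = 0.186 and 0.156) or without array 1 of the untreated cells of its day (0.083 and 0.158).

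Whether the response to PM differed between the days was tested as an interaction. The rise of IL24 was larger on day 4, by 1.54 (SE 0.12) with normal PM and 1.47 with storm PM on the log2 scale. The same held for INSIG1 at 1.53 and 1.77, SCD at 1.31 and 1.52, HMGCS1 at 1.18 and 1.25 and CYP1B1 at 1.10 and 0.98. BDKRB1 stood at 1.49 and 1.29, with means of 2562 and 764.8 in untreated cells on day 1 and day 4, 1178 and 987.4 with normal PM, and 1182 and 863.2 with storm PM. TNFRSF11B fell further on day 4, by 1.62 with normal PM and 1.25 with storm PM, and SULF1 by 0.88 and 0.83. Without the untreated arrays of highest median the calls of SULF1 (adjusted p = 0.0737 and 0.0702), of MMP1 (0.129 and 0.108) and, with storm PM, of BDKRB1 (0.0526) were lost. The rise of MMP1 was smaller on day 4, at -1.06 and -1.16, but for normal PM that call was lost without any 1 normal PM array (adjusted p of 0.0507 and 0.0543 on day 1, and 0.0632 and 0.0524 on day 4). For storm PM it was lost with the compared groups fitted alone (0.0568). Of 18 cholesterol synthesis genes 5 had a higher response on day 4 with normal PM (17 adjusted over the list alone; median log2 0.38; camera adjusted p = 2.15e-25, and adjusted p = 0.00499 with an estimated correlation). With storm PM it was 6 (12 adjusted over the list alone; median log2 0.39; camera adjusted p = 9.01e-25, and adjusted p = 0.00535 with an estimated correlation). Inflammatory cytokines and NF-kB targets were called upward as a list with normal PM, led by IL24 and by CXCL6 at 0.53, but not with an estimated correlation. With storm PM that list was not called. Replication-dependent histones had a lower response on day 4 as a list, with none called alone (medians of -0.16 and -0.13; camera adjusted p = 2.14e-06 and 5.93e-05, and adjusted p = 0.578 and 0.567 with an estimated correlation), but with storm PM not without untreated day 4 array 1 (adjusted p = 0.0864), and in neither with fry (0.18 and 0.199). HMOX1 was not called in either interaction, at 1.08 with normal PM (adjusted p = 0.694) and 1.11 with storm PM (adjusted p = 0.737). Its SE of 0.72 in both includes the wide spread between the storm PM arrays of day 4.

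Interferon-stimulated genes and small nucleolar RNAs had a lower response on day 4 as lists beside the histones, with no member called alone in either interaction, also adjusted over the list alone. The interferon medians were -0.08 with normal PM and -0.04 with storm PM (camera adjusted p = 0.00306 and 0.0458, and adjusted p = 0.353 and 0.567 with an estimated correlation). These calls were lost without any 1 of 2 arrays with normal PM (adjusted p of 0.0505 and 0.0691) and of 5 arrays, treated and untreated, with storm PM (0.0688 to 0.414), with fry (0.122 and 0.199) and, for storm PM, with the replicate block (0.0574). The small nucleolar RNA medians were -0.03 and -0.07 (camera adjusted p = 0.0315 and 0.000816, and adjusted p = 0.749 and 0.604 with an estimated correlation), with SNORD12C at -0.60 in both and SNORD43 at -0.55 with storm PM. Their calls were lost without any 1 of 4 arrays, treated and untreated (adjusted p from 0.0572 to 0.97 with normal PM and from 0.0713 to 0.552 with storm PM), with fry (0.802 and 0.46) and, for normal PM, after quantile normalization (0.0587).

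The interaction called 49 probesets up and 16 down for normal PM, and 49 up and 14 down for storm PM. For normal PM the count of 65 was 43 and 36 without array 1 of the untreated cells on day 1 and day 4, 27 without untreated day 4 array 2, 22 and 15 without array 1 and array 2 of normal PM on day 1, 17 and 13 without those of day 4. It was 43 without either storm PM array of day 1. For storm PM the count of 63 was 39 and 29 without array 1 of the untreated cells on day 1 and day 4, 22 without untreated day 4 array 2, 23 and 20 without array 1 and array 2 of storm PM on day 1, and 28 without storm PM day 4 array 1. It was 38 without either normal PM array of day 1 and 28 without either of day 4. In other settings the counts for normal and storm PM went both ways: 161 and 127 with the array median as a covariate, 119 and 110 with an intensity trend and a robust prior, 30 and 18 with the compared groups fitted alone, and 12 and 16 without the untreated arrays of highest median. For normal PM the count was 100 with an offset of 16, 105 without dim probesets and 103 with probesets of 1 gene symbol, and for storm PM it was 35 with array weights and 30 with the replicate block.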

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

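Of the tests in this part, those of a fall in untreated cells and of a lag on the time course, on 4 lists and on all, for cholesterol genes were chosen only after the result was seen or followed nearly from values already seen, the tests of the array axis, of cholesterol and of lysosomal genes were written once these patterns were known, and the fits with the array median as a covariate or without pairs of untreated arrays were added after seeing the data.

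The response to PM differed between day 4 and day 1 by the test of that difference itself, the interaction in limma. For normal PM 65 probesets passed, and the widest differences were IL24 1.54, INSIG1 1.53, BDKRB1 1.49, AKR1C3 1.48, SCD 1.31 and SELENOW 1.28 on the log2 scale, with TNFRSF11B at -1.62, ANGPTL4 at -1.08, MMP1 at -1.06 and CLSTN2 at -0.91. For storm PM 63 passed, with INSIG1 1.77, AKR1C3 1.67, SCD 1.52, IL24 1.47, BDKRB1 1.29 and HMGCS1 1.25, and with TNFRSF11B at -1.25, MMP1 at -1.16, ANGPTL4 at -1.08 and NPPB at -1. The calls of AKR1C3 and ANGPTL4 were lost when single arrays were left out, 10 and 5 different ones for normal PM and 7 and 9 for storm PM, with adjusted p up to 0.145 and 0.119 for normal PM (without normal PM day 4 array 2 and array 1), and up to 0.1 and 0.115 for storm PM (without storm PM day 1 array 1 and untreated day 4 array 2). Those of MMP1 (without any 1 of the normal PM arrays, adjusted p 0.0507 to 0.0632) and CLSTN2 (7 arrays, up to 0.134 without normal PM day 1 array 2) were lost for normal PM.

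The calls with PM lie along an axis on which untreated day 1 array 1 and day 4 array 2, the arrays of highest median intensity, stand farthest from the PM arrays. With the array median as a covariate the adjusted log2 changes of the 3821 probesets called for any PM kept a median of 0.89 of their size, 130 of the 135 over 1.5-fold stayed called, and 2095 were called in all, which argues against array intensity as the whole source of the larger changes. Of 100 within-day choices of 4 arrays as controls, drawn from 225, only the real one gave as many calls, 3821 against 791 for the highest other. Every other choice mixes PM and untreated arrays on at least 1 day, which widens the spread within groups and lowers the calls. The comparison therefore cannot exclude a chance difference between cultures, which the labels do not tell apart. A part of the smaller changes may still come from that axis: 1557 were called without these arrays, with a median of 0.91 of the full log2 changes, against 2236, 3003 and 5583 calls and 0.98, 1.02 and 1.09 without the other pairs of 1 untreated array per day, while 129 of the 135 over 1.5-fold stayed called. The labels give no batch to test it by, and the effect of the particles stays the candidate explanation for the larger changes, as a hypothesis.

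Between storm and normal PM, 1600 probesets had an unadjusted p under 0.05 in a fit of the 8 PM arrays, and 11 of 34 splits of those arrays gave as many, up to 3171, so chance cannot be excluded there.

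Cholesterol synthesis genes were higher with PM on day 4 by a median of 0.47 on the log2 scale, both kinds together, and a median of 0.46 with the array median as a covariate argues against array intensity as the whole cause. A lag of the PM cultures was tested on the 4 other lists with the largest rise over time (interferon, antigen presentation, complement, hypoxia). Their 74 genes rose by a median of 0.27 and differed with PM on day 4 by -0.06, a reversal of 0.22 (95% bootstrap interval 0 to 0.39) of the one for cholesterol genes. That argues against a lag that moves the pooled genes alike, but not for each list. Complement genes were at -0.15 with PM on day 4 after a rise of 0.25, and hypoxia genes at -0.08 after 0.26. Interferon genes were at -0.04 after 0.32 and antigen presentation genes at 0.06 after 0.24. The untreated arrays of day 4 enter both the rise and the PM difference, with opposite signs. Over all 12 other lists called over time a lag cannot be told apart: the share was 0.13 with a 95% interval of -0.32 to 0.71 over lists, which went both ways. Histones and DNA replication genes were lower with PM on day 4 (-0.17 and -0.14) where they had risen over time. Heat shock genes were higher (0.28) where they had fallen (-0.14). ATF4, lysosomal and iron-handling genes had risen too but were higher (0.32, 0.16 and 0.10). Across all probesets the changes over time and with any PM over both days had a correlation of -0.154, against 0 for simulated unchanged groups. Of those called in both, 559 went opposite ways, 81 rose in both and 90 fell in both, which leaves a lag open. Over time the cholesterol genes fell by 0.46 in untreated cells, while in PM-treated cells their median change was 0.02 (bootstrap SD 0.05), with 5 of 18 called up and 2 down. The difference on day 4 may therefore reflect a fall in untreated cells that was not seen with PM, an explanation drawn from the same values that fit it, and what keeps the genes from falling was not tested.

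Lysosomal genes rose with PM by a median of 0.15. As a set not chosen from the genes seen to rise, 19 genes of the vacuolar proton pump were tested, and their median was 0.09, with 15 above 0, 7 called up and 0 down (camera p = 8.1e-05, and p = 0.0408 with an estimated correlation). This is consistent with a wider rise of lysosomal genes, a hypothesis found and tested on the same arrays. Array intensity cannot be told apart from it for this list, because the list's median was 0.11 with the array median as a covariate, and its bootstrap SD of 0.06 is too wide to tell a loss of most of the rise from a loss of little.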

How the results depend on the processing

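Among the settings of this part, the array median as a covariate, leaving out pairs of 1 untreated array per day, among them the pair with the highest medians, and the crossed replicate block were chosen only after the data had been seen. Of 403 results for named genes 230 kept their direction and call in every setting and none reversed: 8150 single repeats kept the call and 1027 lost it. Of 135 list calls 12 held in every setting: cholesterol synthesis in both PM comparisons of day 4, any PM, both interactions and untreated cells over time, extracellular matrix for normal PM on day 4 and any PM, interferon-stimulated genes in untreated cells over time and for storm against normal PM over both days, and antigen presentation and complement in untreated cells over time. With an estimated correlation 123 list calls ended, with fry 46, without dim probesets 12, after quantile normalization 10, with the covariate 10 and with the replicate block 3. Lists that turned direction did so without 1 storm PM array of day 4: immediate early genes for storm PM on day 4 without array 1 (adjusted p 0.671), and without array 2 NRF2 targets (0.615) and hypoxia genes (0.742) for storm against normal PM on day 4 and, over both days, immediate early genes (0.00605) and ATF4 genes (0.598). Over the arrays left out, the adjusted p of these lists ran from 3.49e-11 to 0.671, from 1.53e-12 to 0.615, from 3.44e-06 to 0.742, from 2.94e-16 to 0.14 and from 1.22e-09 to 0.598.

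All 11 counts stayed within 1.5 times after quantile normalization. With only the compared groups fitted the counts were lower: normal PM 160 on day 1 and 766 on day 4, storm PM 25 and 465, untreated cells over time 178, interactions 30 (normal) and 18 (storm), a fit with fewer arrays. For any PM all arrays are compared, so there is no such separate fit. Requiring 1.5-fold, which can only lower a count, gave 129 and 217 for normal PM on day 1 and day 4, 87 and 200 for storm PM, 181 for untreated cells and 135 for any PM. Without the untreated arrays of highest median, with fewer arrays, the counts were 385 and 767 for normal PM, 176 and 644 for storm PM, 343 for untreated cells, 12 and 16 for the interactions and 1557 for any PM. For any PM the other pairs of untreated arrays gave 2236 (array 1 of both days), 5583 (day 1 array 2 and day 4 array 1) and 3003 (array 2 of both days). With the array median as a covariate they were 1016 for storm PM on day 4, 2320 for untreated cells, 161 and 127 for the interactions and 2095 for any PM. Median centring gave 670 for normal PM and 410 for storm PM on day 1, and moved the share of calls that rose from 62.9% to 73.3% for normal PM on day 4, from 59.4% to 72.6% for storm PM on day 4 and from 56.1% to 72.1% for any PM. An intensity trend with a robust prior gave 970 for storm PM on day 1, 119 and 110 for the interactions, and 1, 0 and 2 for storm against normal PM on day 1, day 4 and both days. Array weights gave 379 for storm PM on day 1, 829 for untreated cells and 35 for the storm interaction. For the normal PM interaction, an offset of 16 gave 100, leaving out dim probesets 105 and only probesets with 1 symbol 103, the latter pair with fewer probesets tested; with 1 symbol storm against normal PM over both days gave 1. The replicate numbers do not pair the arrays alike over all groups (correlation of replicate differences from -0.37 to 0.37 over 15 pairs of groups, 3 of them over 0.1), and as a block they gave 30 for the storm interaction. The differences went together in untreated and storm PM day 1 (0.37), and in normal PM day 1 and untreated day 4 (0.24). Between these pairs they went opposite ways (-0.37 to -0.30), so PM arrays of day 1 share part of the spread of the untreated arrays, crossed by number. A crossed block gave 1076 for normal PM on day 1, 0 for storm against normal PM on day 1 and 1550 for untreated cells. Except where fewer arrays or probesets or the threshold itself account for it, the cause was not tested.

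Leaving out each array in turn gave 316 to 1304 calls for normal PM and 136 to 1179 for storm PM on day 1, 555 to 1789 and 552 to 1969 on day 4, 712 to 1340 for untreated cells, 13 to 71 and 20 to 53 for the interactions and 2157 to 5048 for any PM. For storm against normal PM the ranges were 0 to 0 on day 1, 0 to 14 on day 4 and 0 to 17 over both days. An array left alone in its group is assumed to vary like the other groups. The correlations of responses ran from 0.75 to 0.903 and 0.777 to 0.894 between kinds of PM on day 1 and day 4, and from 0.384 to 0.528 and 0.382 to 0.535 between days. The table holds no detection call, so signal over background could be judged only by leaving out probesets with a mean under the 40th percentile.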

Other observations

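No test in this part was chosen after its result was seen, but the genes named here were. Genes of cell death and of p53 went both ways with PM over both days, and neither list was called in any comparison. Of 21 measured p53 targets 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.956), with the stress cytokine GDF15 at 0.56 (SE 0.08) and TP53INP1 at -0.27 (SE 0.04). CDKN1A, the p21 inhibitor, was at 0.21 (SE 0.07, adjusted p = 0.0918). Of 17 apoptosis regulators 2 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.636), with PMAIP1 at 0.36, XIAP at 0.23 and BMF at -0.35. Mitotic genes were not called as a list (none of 25 rose and 2 fell, likewise adjusted over the list alone; median log2 -0.02; camera adjusted p = 0.409), MKI67 being at -0.12. In untreated cells over time 4 of 25 fell (1 rose and 9 fell adjusted over the list alone; median log2 -0.12; camera adjusted p = 0.00529, and adjusted p = 0.436 with an estimated correlation), a call lost without day 1 array 2 (0.168) or day 4 array 2 (0.157). Chaperones of the endoplasmic reticulum were near the threshold, with 1 of 18 called, DNAJC3 at 0.20 (also 1 adjusted over the list alone; median log2 0.05; camera adjusted p = 0.0531). They were called upward with storm PM on day 1 (median log2 0.05; camera adjusted p = 0.0486, and adjusted p = 0.374 with an estimated correlation), but not with fry (0.14), after quantile normalization (0.168), without dim probesets (0.102), with the array median as a covariate (0.216) or without any 1 of 8 arrays (up to 0.162).

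Growth factor genes went both ways with PM. Of 11 EGF receptor ligands and growth factors 3 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.4), with VEGFA at 0.33, PDGFA at 0.29 and PDGFB at -0.22. None of 18 ribosomal protein genes was called, also adjusted over the list alone, in limma over both days (median log2 0.03; camera adjusted p = 0.109). That list was called upward with normal PM on day 4 (median log2 0.05; camera adjusted p = 0.0143, and adjusted p = 0.191 with an estimated correlation), a call lost without untreated day 4 array 2 (0.0545) and without dim probesets (0.059). Of 21 hypoxia genes 5 rose and 7 fell (5 and 9 adjusted over the list alone), with CA12, a carbonic anhydrase, at 0.44 and ADM, adrenomedullin, at -0.63. Their response to storm PM was lower on day 4 as a list (median log2 -0.09; camera adjusted p = 0.0138, and adjusted p = 0.604 with an estimated correlation), a call lost with fry (0.248) and without any 1 of 4 arrays, treated and untreated (0.0718 to 0.414). Of 28 interferon-stimulated genes 3 rose and 3 fell (4 and 4 adjusted over the list alone), with a median of 0.01 and a mean of -0.01. Of 11 antigen presentation genes 2 rose and 1 fell (4 and 2 adjusted over the list alone). Leukocyte markers were not called as a list (1 of 13 rose and 1 fell, likewise adjusted over the list alone; camera adjusted p = 0.612): CD68, a lysosomal protein, was at 0.34 and CD14, a receptor for bacterial lipopolysaccharide, at -0.41. None of 10 endothelial markers was called, also adjusted over the list alone (median log2 -0.05; camera adjusted p = 0.612).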
